A study of Mus musculus with 23 samples.

How the data were processed

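Polyadenylated RNA was measured in sorted OT-I and OT-II T cells of C57BL/6 mice. Per the labels, RNA of 3 mice was pooled for each library after extraction and turned into cDNA with the SmartSeq protocol. Nothing in the sources used here says that libraries are separate in any way beyond these pools of 3 mice, nor whether an OT-I and an OT-II library with the same replicate number came from the same mice. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq and pseudoaligned with kallisto 0.46.1 on genome build GRCm38. The authors deposited 1 table of estimated counts, with 21900 protein-coding genes and 23 libraries. All its values are whole numbers, and neither the rounding nor the summing of transcripts to genes is stated. The annotation release and the strand of the libraries are not given in the sources used here. Of the identifiers, 21806 are in GENCODE M21, which gave the positions; 27 symbols look like dates from a spreadsheet and 32 symbols occur more than once, so genes were joined by identifier.

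Library totals ran from 26.6 M to 73.5 M counts. In these libraries a count of 0 allows 0.0408 to 0.113 CPM (3 counts of the total, counting error only). Reads without molecular identifiers are not independent molecules, so this floor leaves out amplification.

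Groups followed the labels: cell type by treatment, with 3 libraries each and 2 for OT-II with higher-dose OVA. The titles carry the numbers 0.5 and 5 for the OVA groups without a unit. Each cell type was fitted on its own with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr with a minimum count of 10 and a minimum total of 15, 1 coefficient per group and no block, quasi-likelihood test). All 12 comparisons of 2 treatments within a cell type were made, and 3 differences between the OT-I and OT-II responses to A8B1-OVA were tested as interaction contrasts in 1 fit of all libraries. After filtering, 14080 genes were tested in OT-I, 14757 in OT-II and 15235 in the joint fit. The common dispersion was 0.0782, 0.0876 and 0.0878. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. CPM in the text are edgeR values with TMM factors, given as mean and SD over libraries, whereas sums of markers and the plots of levels and markers use the plain library total.

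Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, on log2 CPM with a prior count of 2, and again with an estimated correlation and with fry; p-values were adjusted over the lists of a comparison. A list with fewer than 5 tested genes was not tested. The 25 lists were: cell cycle, TCR signalling and early activation, inhibitory receptors, exhaustion-associated transcription factors, anergy-associated, follicular helper-associated, regulatory T cell-associated, naive and memory-associated, cytotoxic and effector, chemokine receptors and homing, helper cytokines, interferon-stimulated, glycolysis, oxidative phosphorylation, cholesterol synthesis and uptake, apoptosis regulators, ribosomal proteins, handling stress and heat shock, CD4 and CD8 lineage genes, and markers of B, myeloid, NK, erythroid and platelet cells. With an estimated correlation 3 of the 134 list calls within the cell types held. The lists, the comparisons, the test and the rule for named genes were fixed beforehand. Some genes stand in several lists. Irf4 is in those of TCR signalling and of exhaustion-associated transcription factors, and Jun in those of TCR signalling and of handling stress. Calls of such lists are therefore not separate support for one another.

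Named genes were, in each comparison of A8B1-OVA with another treatment, the 8 called genes with the highest and the 8 with the lowest log2 fold change among those with a mean of at least 10 CPM and no overlap between the libraries of the groups. For the other comparisons within a cell type the rule took 4 and 4, and for the interaction contrasts 4 and 4 without the overlap condition. Up to 4 members with the lowest adjusted p were added from each list with a count in the text, and a panel of 27 genes in any comparison. Of those named by this rule, genes whose call and size held without any 1 library were preferred as examples, a choice made after the data were seen. Of 429 genes looked at, 94 share at least 10% of their sequence with another gene by 31-base words, and such genes were mostly left out.

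The test was tried on counts simulated once per comparison around a single mean per gene over all libraries, with changes put into the first group. No simulated library carried RNA of other cells, as some real ones do, so the shares below may not hold for the real libraries. For A8B1-OVA against saline it recovered 40.4% of 2-fold and 75.5% of 4-fold changes in OT-I and 59.8% and 65% in OT-II, and 33% of 2-fold differences between the responses. For molar-equivalent OVA against saline it recovered 45.8% of 2-fold changes in OT-I and 44.3% in OT-II. At most 8.08% of its calls were false in the comparisons simulated.

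The alternatives set before the data were examined were DESeq2 1.42.0, DESeq2-type (RLE) size factors in edgeR, no filter on low counts, only the libraries of the groups compared, replicate number as a block, and leaving out each library in turn. Robust empirical Bayes, fits without libraries with raised markers of other cells, and thinning of OT-I libraries to the smallest total were chosen after seeing the data.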

Results

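OT-I cells are CD8 T cells and OT-II cells are CD4 T cells, each with a transgenic receptor for a peptide of ovalbumin (OVA). Both were transferred into C57BL/6 mice, which 1 day later received 1 ug of A8B1-OVA, the molar equivalent of free OVA, a higher dose of free OVA, or saline. The series title places the work in antigen targeting to erythrocytes and T cell anergy, a state in which a T cell that has met its antigen responds poorly to it. What A8B1 is was not given in the sources used here. The cells were sorted 5 days after transfer from pooled spleens and lymph nodes, and the RNA of 3 mice was pooled for each library. The 23 libraries make 8 groups, with n = 3 in each except OT-II with higher-dose OVA, which has n = 2 (replicates 2 and 3).

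The deposited table held 21900 protein-coding genes. Total counts per library ran from 26.6 M to 73.5 M. In OT-I they ran from 53 M to 73.5 M with A8B1-OVA, 26.6 to 56 with molar-equivalent OVA, 33.5 to 34.3 with higher-dose OVA and 53.9 to 68.2 with saline. In OT-II they ran from 57.5 M to 64.8 M with A8B1-OVA, 49 to 54.8 with molar-equivalent OVA, 52.3 to 62.1 with higher-dose OVA and 45.1 to 57.4 with saline. Between 15182 and 16020 genes had a count in a library, and the 10 most abundant genes took 4.65% to 6.81% of the counts. On the first principal component of the OT-I libraries (28.1% of the variance) the A8B1-OVA replicates lay at -61, -68.1 and -35.6 and the saline replicates between 26.8 and 37.3. On that of the OT-II libraries (21.4%) the A8B1-OVA replicates lay at -60.4, -62.3 and -38.5 and the saline replicates between 22.2 and 29.

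The lineage genes followed the cell labels. Cd8a, a chain of the CD8 co-receptor, had group means of 987 to 1220 CPM (counts scaled to a common library total) in OT-I and 1.76 to 3.54 in OT-II, and Cd4 had 577 to 691 in OT-II and 1.72 to 54.1 in OT-I. The OT-I Cd4 mean of 54.1 ± 91.8 (SD, n = 3), with higher-dose OVA, came from replicate 1. Markers of other cells stood apart in single libraries. The summed B cell markers reached 3530 CPM and the myeloid markers 1610 in OT-I molar-equivalent OVA replicate 2, and the myeloid markers reached 872 in OT-I saline replicate 1, against 288 to 582 in the other OT-I libraries. In OT-II the myeloid sum was 1370 in saline replicate 1 and the B cell sum 1530 in molar-equivalent OVA replicate 3. These 4 libraries and OT-I higher-dose OVA replicate 1 are called the raised-marker libraries, and fits without them were added after the data were seen.

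**Figure D1:**
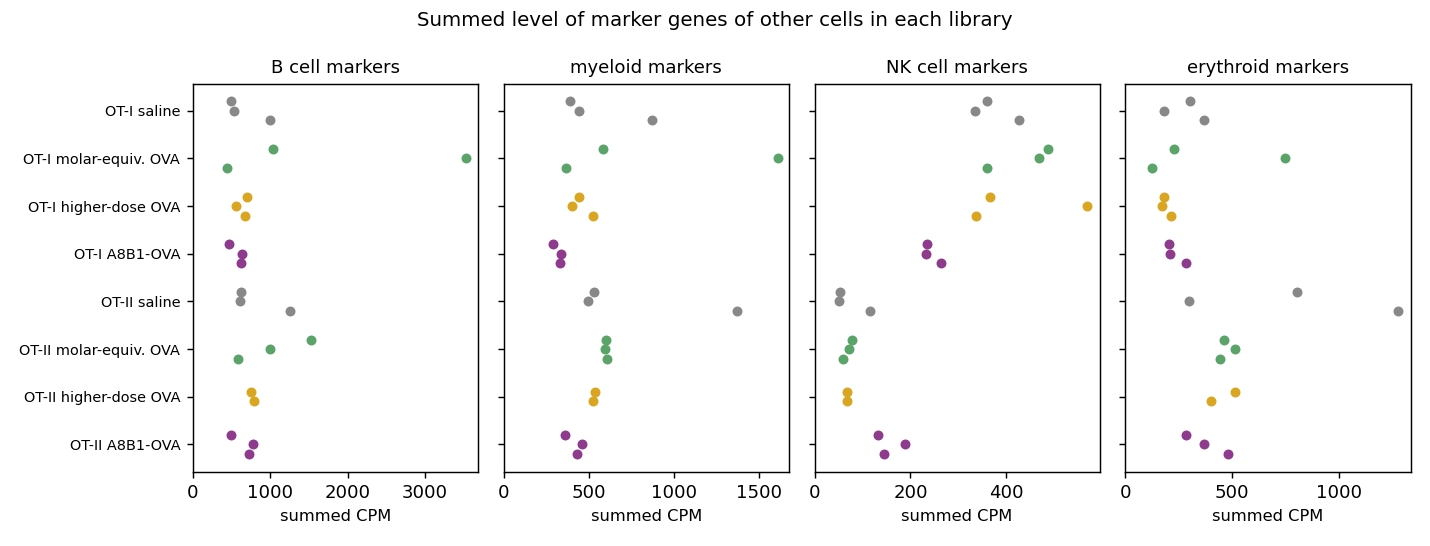
Summed CPM of the B cell, myeloid, NK cell and erythroid marker lists in each of the 23 libraries, 1 point per library, by cell type and treatment on linear axes from 0. OT-I molar-equivalent OVA replicate 2 has the highest B cell sum, 3530 CPM.

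**Figure D2:**
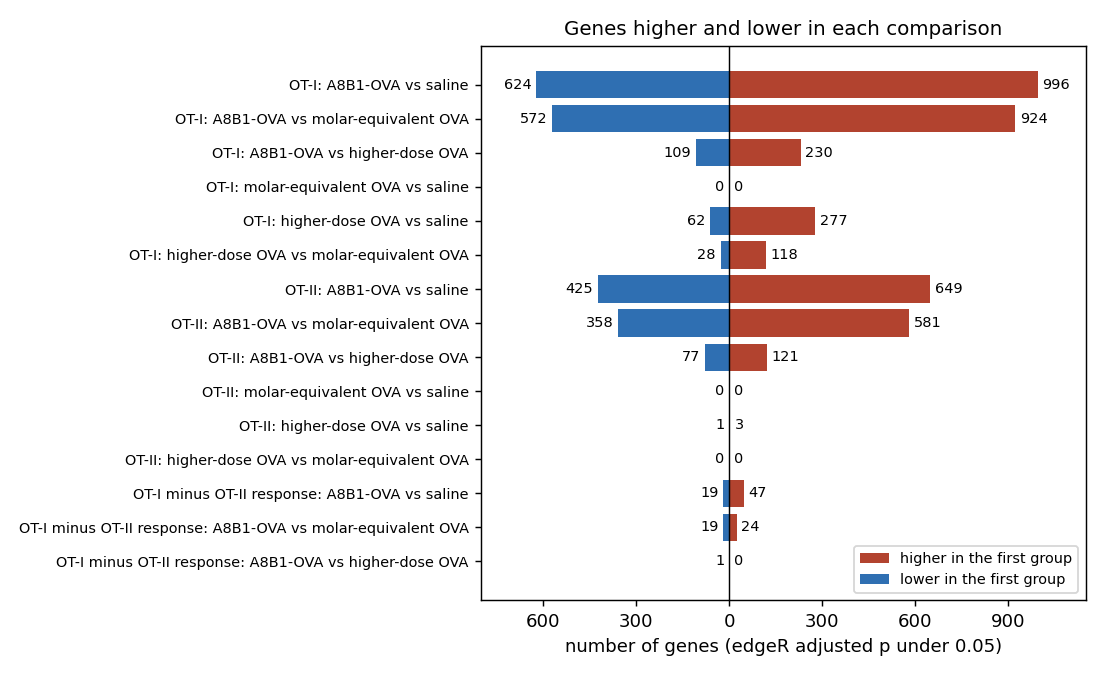
Number of genes past the edgeR threshold in each of the 15 comparisons, higher to the right and lower to the left. A8B1-OVA against saline has 996 higher and 624 lower genes in OT-I and 649 and 425 in OT-II.

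A8B1-OVA against saline in OT-I cells asks what it did to antigen-specific CD8 T cells. Lag3, an inhibitory receptor that binds MHC class II, was at 23.4 ± 8.3 CPM (SD, n = 3) against 0.438 ± 0.0868 in saline (log2 fold change 5.73 ± 0.57 SE, adjusted p = 9.1e-05). Pdcd1, which encodes PD-1, was at 77.9 ± 20.4 against 3.96 ± 0.879 (4.30 ± 0.41, adjusted p = 8.1e-05). Izumo1r, the folate receptor 4 gene found on anergic and regulatory T cells, was at 131 ± 37.3 against 5.82 ± 1.56 (4.49 ± 0.42). The highest fold change among these genes was that of Zbtb32, a transcriptional repressor that limits T cell proliferation, at 63.3 ± 15.8 against 1.03 ± 0.607 (5.94 ± 0.77). Mki67, a proliferation marker, rose from 5.94 ± 2.91 to 93.9 ± 45, while Il7r, the survival receptor of resting T cells, fell from 422 ± 10.2 to 127 ± 36.3 (-1.74 ± 0.20). On GRCm38 Lag3 spans 124904361 to 124911705 of chromosome 6, Pdcd1 94038305 to 94052553 of chromosome 1, and Zbtb32 30589681 to 30598909 of chromosome 7.

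Of the 17 tested inhibitory receptor genes 8 were higher, 1 was lower and 8 did not pass (10 higher and 1 lower adjusted over the list alone; camera adjusted p = 9.5e-05, adjusted p = 0.19 with an estimated correlation). Besides Lag3 and Pdcd1 they included Cd200 (4.05 ± 0.31) and Ctla4, which competes with Cd28 for its ligands (2.96 ± 0.37). Tigit (1.25, adjusted p = 0.063) and Havcr2, which encodes TIM-3 (-0.72, adjusted p = 0.65), did not pass. In the cell cycle list 49 of 50 genes were higher and 0 lower (50 higher adjusted over the list alone), with a median log2 fold change of 3.21 (camera adjusted p = 6.5e-42, adjusted p = 0.17 with an estimated correlation). Bub1b, a spindle checkpoint kinase, rose by 3.96 ± 0.41. Exhaustion-associated transcription factors gave 8 higher, 1 lower and 7 not passed (10 and 2 adjusted over the list alone; camera adjusted p = 0.0006, adjusted p = 0.083 with an estimated correlation), among them Irf4 (1.85 ± 0.19) and Tox (0.58 ± 0.11). Anergy-associated genes gave 10 higher, 2 lower and 15 not passed (11 and 3 adjusted over the list alone; camera adjusted p = 0.0089, adjusted p = 0.45 with an estimated correlation). They included Izumo1r, Nrp1, the neuropilin gene (47.7 ± 0.601 against 3.05 ± 0.182 CPM), and Egr2, an early growth response factor induced by receptor signalling (33.4 ± 3.33 against 10.8 ± 0.835).

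T cell receptor (TCR) signalling and early activation genes went both ways. Among them were 10 higher, 6 lower and 14 not passed (14 and 7 adjusted over the list alone; camera adjusted p = 0.029, adjusted p = 0.58 with an estimated correlation). Tnfrsf9, the co-stimulatory receptor 4-1BB, rose from 30.3 ± 7.45 to 184 ± 35.3 CPM. Follicular helper-associated genes gave 12 higher, 1 lower and 4 not passed (12 and 3 adjusted over the list alone; camera adjusted p = 3.5e-06, adjusted p = 0.12 with an estimated correlation). Regulatory T cell-associated genes gave 7 higher, 1 lower and 15 not passed (8 and 1 adjusted over the list alone; camera adjusted p = 0.011, adjusted p = 0.45 with an estimated correlation). Foxp3 itself was at -0.44 (adjusted p = 0.69). Helper cytokines gave 3 higher, 1 lower and 11 not passed (6 and 1 adjusted over the list alone; camera adjusted p = 0.03, adjusted p = 0.45 with an estimated correlation). Naive and memory-associated genes gave 4 higher and 11 lower of 29 (5 and 14 adjusted over the list alone; camera adjusted p = 0.0063, adjusted p = 0.45 with an estimated correlation). Tcf7, a factor of resting and stem-like T cells, was at 0.22 ± 0.10 (adjusted p = 0.17). Cytotoxic and effector genes gave 4 higher, 2 lower and 22 not passed (4 and 2 adjusted over the list alone; camera adjusted p = 0.5, with a median of -0.02 against a mean of 0.3 and a test direction of higher). The higher ones included the chemokines Xcl1 (141 ± 45.2 against 11.9 ± 3.35 CPM) and Ccl4 (81.3 ± 26.6 against 9.74 ± 3.94). Gzmb, the granzyme B gene of cytotoxic granules, stayed at 6.63 ± 1.74 against 6.51 ± 1.09 (0.02 ± 0.56, adjusted p = 0.98).

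Glycolysis genes gave 9 higher, 0 lower and 17 not passed (10 higher adjusted over the list alone; camera adjusted p = 0.00081, adjusted p = 0.19 with an estimated correlation). Oxidative phosphorylation genes gave 3 higher, 0 lower and 61 not passed (0 adjusted over the list alone; camera adjusted p = 1.5e-06, adjusted p = 0.61 with an estimated correlation). Of the 75 ribosomal protein genes 0 passed (camera adjusted p = 0.0035 higher, adjusted p = 0.74 with an estimated correlation). Interferon-stimulated genes gave 1 higher and 4 lower of 40 (1 and 7 adjusted over the list alone; camera adjusted p = 0.029, adjusted p = 0.69 with an estimated correlation). Handling stress and heat shock genes gave 1 higher and 9 lower of 22 (2 and 10 adjusted over the list alone; camera adjusted p = 0.0035, adjusted p = 0.58 with an estimated correlation). Their summed level was 5990 to 7420 CPM with A8B1-OVA against 9470 to 11900 with saline. The camera test passed neither for apoptosis regulators (6 higher, 3 lower of 30, adjusted p = 0.25), chemokine receptors and homing (5 and 6 of 30, adjusted p = 0.35) nor cholesterol synthesis and uptake (4 and 0 of 25, adjusted p = 0.2). It also did not pass for CD8 lineage genes (1 and 1 of 8, adjusted p = 0.35) and CD4 lineage genes (1 and 1 of 7, adjusted p = 0.41). Of the markers of other cells, the camera test passed as lower for those of myeloid cells (0 higher, 1 lower of 24, adjusted p = 0.0064, adjusted p = 0.66 with an estimated correlation) and NK cells (1 and 1 of 15, adjusted p = 0.033, adjusted p = 0.6 with an estimated correlation). Neither call held without the raised-marker libraries (adjusted p = 0.085 and 0.09). Platelet (0 of 6, adjusted p = 0.2), erythroid (0 of 19, adjusted p = 0.58) and B cell markers (1 higher of 20, adjusted p = 0.69) did not pass. The called members were Cebpb of the myeloid list (24 against 67.1 CPM in saline) and Cd22 of the B cell list (42.9 against 8.73). Of the NK cell list they were Cd7 (113 against 259) and Eomes (112 against 64.8). Their RNA may come from the OT-I cells themselves, so these lists may not measure other cells alone.

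In this comparison edgeR called 1620 of 14080 tested genes, 996 higher and 624 lower, and 543 of the higher and 179 of the lower ones differed by over 2-fold. Leaving out A8B1-OVA replicate 1, 2 or 3 gave 1070, 674 and 2569 genes, and leaving out saline replicate 1, 2 or 3 gave 901, 889 and 721. Without the raised-marker libraries 977 genes were called, 654 higher and 323 lower.

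**Figure D3:**
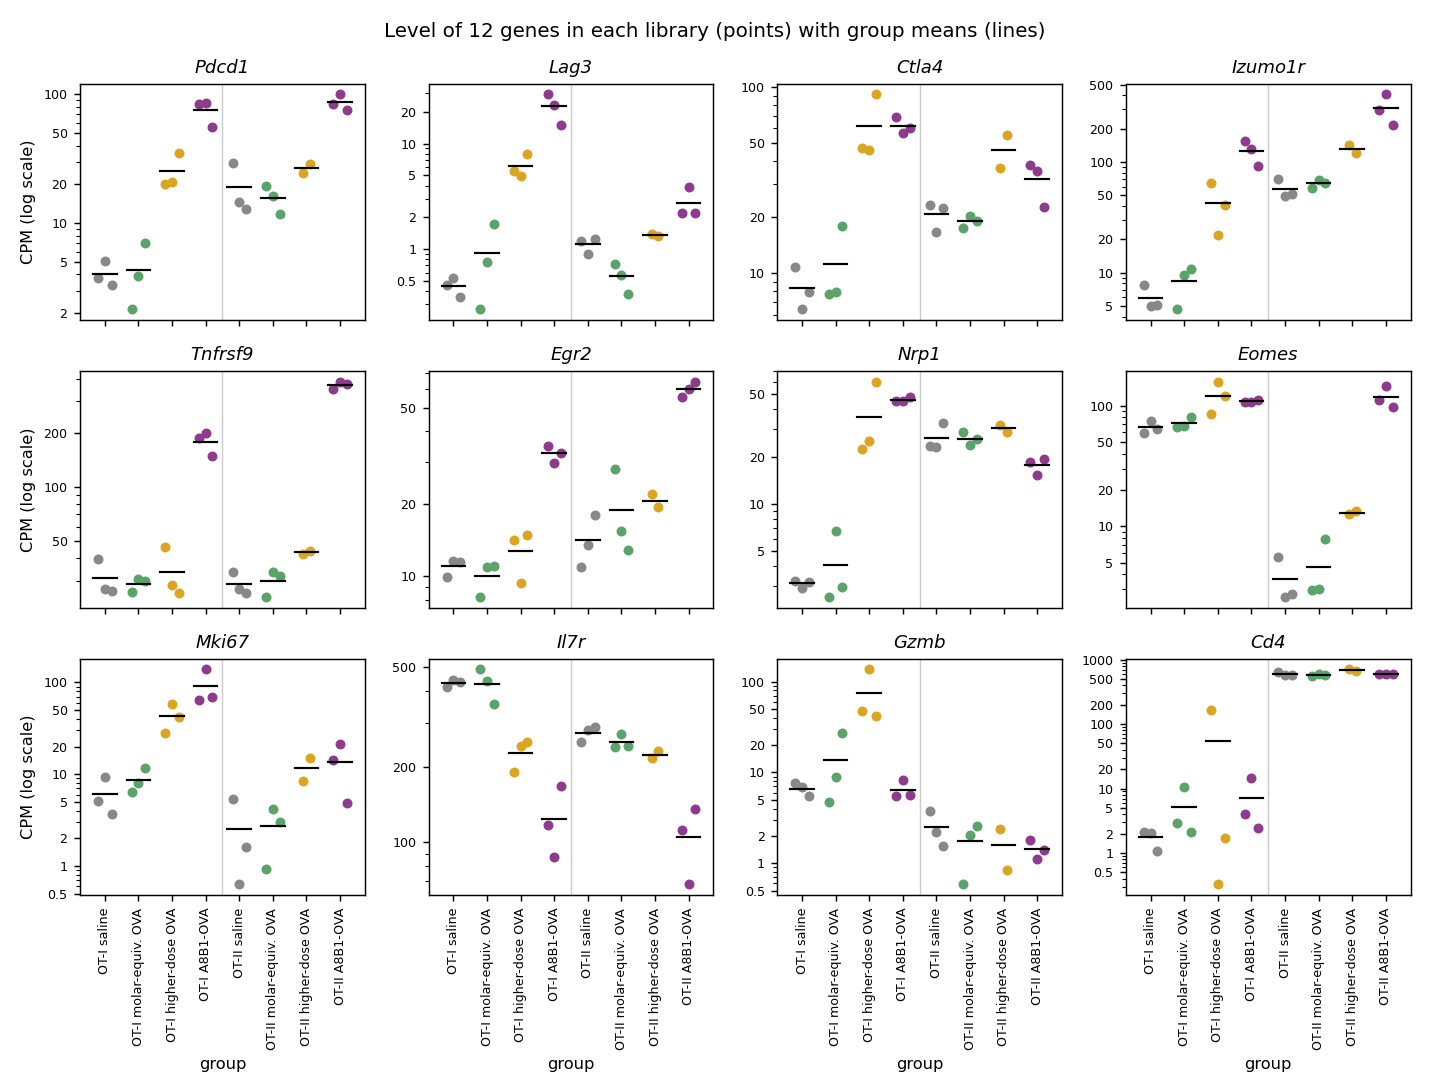
CPM of 12 genes in each library by cell type and treatment on a log axis, with 1 point per library and a line at each group mean. Pdcd1 and Tnfrsf9 are highest with A8B1-OVA in both cell types, whereas Eomes in OT-II is at 117 CPM with A8B1-OVA and at 3.66 with saline.

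A8B1-OVA against molar-equivalent OVA in OT-I cells asks what differed from free OVA at the same molar amount. Izumo1r was at 131 ± 37.3 CPM (SD, n = 3) against 8.23 ± 3.25 with free OVA (log2 fold change 4.0 ± 0.42 SE, adjusted p = 0.00016). Cd200, an inhibitory ligand, was at 95.6 ± 29.9 against 7 ± 2.28 (3.78 ± 0.31). Tnfrsf9 rose from 28.3 ± 2.42 to 184 ± 35.3 (2.71 ± 0.23, adjusted p = 8.9e-05), and Ctla4 from 11.1 ± 6.02 to 63.9 ± 8.27 (2.53 ± 0.36). Il7r fell from 421 ± 63.5 to 127 ± 36.3 (-1.73 ± 0.20), as did Bcl2, which protects from apoptosis, from 285 to 105 (-1.44 ± 0.20). Pdcd1 had 4.19 ± 0.41 (adjusted p = 0.00014), and 4.79 without molar-equivalent OVA replicate 3.

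Cell cycle genes gave 49 higher and 0 lower of 50 (50 higher adjusted over the list alone; median 2.91, camera adjusted p = 3.8e-38, adjusted p = 0.21 with an estimated correlation). Mki67 rose by 3.45 ± 0.43. TCR signalling and early activation genes gave 13 higher, 1 lower and 16 not passed (14 and 4 adjusted over the list alone; camera adjusted p = 0.0017, adjusted p = 0.33 with an estimated correlation). Egr2 (1.76 ± 0.19) and Irf4 (1.66) were examples. Inhibitory receptors gave 7 higher and 2 lower of 17 (8 and 3 adjusted over the list alone; camera adjusted p = 0.0017, adjusted p = 0.33 with an estimated correlation). Anergy-associated genes gave 10 higher, 2 lower and 15 not passed (11 and 3 adjusted over the list alone; camera adjusted p = 0.0039, adjusted p = 0.33 with an estimated correlation). Exhaustion-associated transcription factors gave 8 higher and 1 lower of 16 (9 and 3 adjusted over the list alone; camera adjusted p = 0.0008, adjusted p = 0.085 with an estimated correlation). Naive and memory-associated genes gave 3 higher and 11 lower of 29 (6 and 13 adjusted over the list alone; camera adjusted p = 0.0075, adjusted p = 0.38 with an estimated correlation). Cytotoxic and effector genes gave 4 higher and 3 lower of 28 (camera adjusted p = 0.81), and Xcl1 was again the example among the higher ones (3.75 ± 0.34). Beside these groups 4 of 24 myeloid markers were lower (16 adjusted over the list alone; camera adjusted p = 0.00014, adjusted p = 0.59 with an estimated correlation). Of the B cell markers 0 of 20 passed (17 lower adjusted over the list alone; camera adjusted p = 0.0059, adjusted p = 0.59 with an estimated correlation, and adjusted p = 0.37 without the raised-marker libraries). NK cell markers gave 1 higher and 4 lower of 15 (camera adjusted p = 0.006, adjusted p = 0.49 with an estimated correlation) and platelet markers 1 lower of 6 (camera adjusted p = 0.022, adjusted p = 0.33 with an estimated correlation), and neither list passed without the raised-marker libraries (adjusted p = 0.12 and 0.095).

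Against molar-equivalent OVA 1496 of 14080 genes were called in OT-I, 924 higher and 572 lower. The count was 997, 575 and 2181 without A8B1-OVA replicate 1, 2 or 3, and 973 without molar-equivalent OVA replicate 1. DESeq2 called 2457, and edgeR with only the libraries of these groups 575.

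A8B1-OVA against higher-dose OVA in OT-I cells sets it beside free OVA at a larger amount. Xcl1 was at 141 ± 45.2 CPM (SD, n = 3) against 12.3 ± 2.28 (log2 fold change 3.51 ± 0.33 SE, adjusted p = 0.00033). Ccl4, a chemokine that activated T cells secrete, was at 81.3 ± 26.6 against 11.1 ± 0.129 (2.87 ± 0.35). Tnfrsf9 was at 184 ± 35.3 against 33.3 ± 10.1 (2.47 ± 0.23), and Egr2 at 33.4 ± 3.33 against 12.8 ± 2.91 (1.38 ± 0.19, adjusted p = 0.0038). Gpr183, an oxysterol receptor that guides lymphocyte position, was lower, at 71 ± 5.19 against 152 ± 15.1 (-1.10 ± 0.12). Ctla4 was at 63.9 ± 8.27 and 62.2 ± 26.8 (0.04 ± 0.34, adjusted p = 0.97), and Lag3 had 1.91 ± 0.47 (adjusted p = 0.052). Xcl1 spans 164931644 to 164935527 of chromosome 1 and Tnfrsf9 150914562 to 150946102 of chromosome 4.

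Of the 28 cytotoxic and effector genes 2 were higher with A8B1-OVA, 10 were lower and 16 did not pass (3 and 14 adjusted over the list alone; median -0.91, camera adjusted p = 7.3e-05, adjusted p = 0.6 with an estimated correlation). Gzmb was at 6.63 ± 1.74 against 76 ± 54.5 (-3.52 ± 0.60, adjusted p = 0.014). Its call was lost without A8B1-OVA replicate 1 (-3.42, adjusted p = 0.065) or 2 (-3.73, adjusted p = 0.067). Without higher-dose OVA replicate 2 it was -2.71 (adjusted p = 0.046). Gzmm, another granzyme gene, was at 4.89 against 29 (-2.57 ± 0.37, adjusted p = 0.0059; -2.43 and adjusted p = 0.052 without A8B1-OVA replicate 2). Cell cycle genes gave 22 higher and 0 lower of 50 (49 higher adjusted over the list alone; median 1.5, camera adjusted p = 5.1e-27, adjusted p = 0.6 with an estimated correlation). Chemokine receptors and homing genes gave 0 higher and 7 lower of 30 (2 and 10 adjusted over the list alone; camera adjusted p = 0.00061, adjusted p = 0.6 with an estimated correlation). Inhibitory receptors gave 4 higher and 2 lower of 17 (5 and 3 adjusted over the list alone; camera adjusted p = 0.25). Of the 75 ribosomal protein genes 0 passed, and their median was 0.65 (camera adjusted p = 6.1e-13, adjusted p = 0.61 with an estimated correlation). Beside these groups, Cd4 and other OT-II genes were raised in higher-dose OVA replicate 1. Myeloid markers gave 1 lower of 24 (camera adjusted p = 0.0016) and NK cell markers 2 lower of 15 (camera adjusted p = 0.032), each at adjusted p = 0.61 with an estimated correlation, and both list calls held without the raised-marker libraries. The platelet markers, 0 of 6 called (camera adjusted p = 0.044 lower, adjusted p = 0.6 with an estimated correlation), did not pass there (adjusted p = 0.083). For the NK cell markers that fit is no check on RNA of other cells. Their sum was highest in higher-dose OVA replicate 2, which was kept, at 569 CPM against 336 and 366 in replicates 1 and 3.

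Against higher-dose OVA 339 of 14080 genes were called in OT-I, 230 higher and 109 lower, and 2661 had an unadjusted p under 0.05. The count was 106, 38 and 1487 without A8B1-OVA replicate 1, 2 or 3, and 109, 108 and 67 without higher-dose OVA replicate 1, 2 or 3. DESeq2 called 1202, edgeR with only the libraries of these groups 210, and edgeR without the raised-marker libraries 62.

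A8B1-OVA against saline in OT-II cells asks the same of antigen-specific CD4 T cells. Eomes, a T-box transcription factor of cytotoxic and memory T cells, was at 117 ± 26.5 CPM (SD, n = 3) against 3.66 ± 1.74 in saline (log2 fold change 5.00 ± 0.42 SE, adjusted p = 5.7e-05). The predicted gene Gm33460 lies antisense to it, and the strand of the reads is not stated. Tnfrsf9 was at 366 ± 19.3 against 28.7 ± 4.66 (3.67 ± 0.15, adjusted p = 1.5e-07), and Izumo1r at 306 ± 101 against 57.2 ± 12 (2.42 ± 0.22). Pdcd1 was at 86 ± 13.8 against 19.1 ± 9.45 (2.17 ± 0.29, adjusted p = 0.0012), and Egr2 at 59.4 ± 3.61 against 14.1 ± 3.62 (2.07 ± 0.27). Klf2, a factor that keeps T cells quiescent and circulating, fell from 759 ± 26.9 to 315 ± 25.4 (-1.27 ± 0.10, adjusted p = 3.1e-05), and Dntt, the terminal transferase of recent thymic emigrants, from 76.8 ± 5.18 to 22.1 ± 2.71 (-1.80 ± 0.12).

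TCR signalling and early activation genes gave 11 higher, 3 lower and 16 not passed (16 and 5 adjusted over the list alone; camera adjusted p = 7.4e-05, adjusted p = 0.11 with an estimated correlation). Egr3 was at 25.3 against 6.78 CPM (1.90 ± 0.26). Exhaustion-associated transcription factors gave 7 higher and 1 lower of 16 (10 and 2 adjusted over the list alone; camera adjusted p = 2.7e-05, adjusted p = 0.11 with an estimated correlation). Tox was at 237 ± 34.7 against 111 CPM (1.09 ± 0.11). Follicular helper-associated genes gave 10 higher and 2 lower of 22 (11 and 4 adjusted over the list alone; camera adjusted p = 0.0012, adjusted p = 0.3 with an estimated correlation). They included Cxcr5, the receptor that leads T cells to B cell follicles (3.27 ± 0.34). Inhibitory receptors gave 4 higher and 1 lower of 17 (8 and 1 adjusted over the list alone; camera adjusted p = 0.011, adjusted p = 0.45 with an estimated correlation). Lag3 (1.28, adjusted p = 0.079) and Ctla4 (0.62, adjusted p = 0.12) did not pass. Anergy-associated genes gave 9 higher, 5 lower and 13 not passed (12 and 7 adjusted over the list alone; camera adjusted p = 0.063, with a median of -0.01 against a mean of 0.23 and a test direction of higher). Dgkz, a diacylglycerol kinase that dampens receptor signalling, rose from 512 to 861 CPM (0.75 ± 0.09). Cell cycle genes gave 23 higher and 0 lower of 50 (44 higher adjusted over the list alone; median 1.85, camera adjusted p = 1.8e-19, adjusted p = 0.3 with an estimated correlation). Mcm5, a helicase subunit of DNA replication, was at 183 against 68.5 CPM.

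Of the 40 interferon-stimulated genes 0 were higher, 11 were lower and 29 did not pass (19 lower adjusted over the list alone; median -0.4, camera adjusted p = 8e-10, adjusted p = 0.34 with an estimated correlation). Bst2, an antiviral membrane protein, was at 70.8 against 116 CPM (-0.72 ± 0.13). Naive and memory-associated genes gave 4 higher and 9 lower of 29 (4 and 16 adjusted over the list alone; camera adjusted p = 2.7e-05, adjusted p = 0.11 with an estimated correlation). Il7r was at 104 ± 32.4 against 275 ± 17.4 CPM (-1.40 ± 0.18) and S1pr1, the receptor for exit from lymph nodes, at 554 against 1020 (-0.88 ± 0.11). Cytotoxic and effector genes gave 1 higher and 4 lower of 28 (1 and 5 adjusted over the list alone; camera adjusted p = 0.012, adjusted p = 0.39 with an estimated correlation, and adjusted p = 0.09 without the raised-marker libraries). Prf1, the perforin gene, was at 20.7 against 45.7 CPM (-1.14 ± 0.14). Of the 24 myeloid markers 7 were lower (12 adjusted over the list alone; camera adjusted p = 4.2e-05, adjusted p = 0.47 with an estimated correlation, and adjusted p = 0.082 without the raised-marker libraries). Of the 19 erythroid markers 1 was lower (camera adjusted p = 0.02, adjusted p = 0.52 with an estimated correlation, and adjusted p = 0.46 without the raised-marker libraries). Their sum was 1280, 298 and 807 CPM in the saline replicates and 286 to 482 with A8B1-OVA. The summed NK cell markers, a list that holds Eomes, were at 132 to 189 CPM with A8B1-OVA and 51.8 to 115 with saline.

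Against saline 1074 of 14757 tested genes were called in OT-II, 649 higher and 425 lower, with 274 and 95 of them over 2-fold. The count was 668 and 626 without A8B1-OVA replicate 1 or 2, and 694 and 578 without saline replicate 2 or 3. DESeq2 called 1892.

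A8B1-OVA against molar-equivalent OVA in OT-II cells gave Olfml3, a secreted olfactomedin-like protein, the highest fold change among the genes named here, at 37.4 ± 18.3 CPM (SD, n = 3) against 0.71 ± 0.392 (log2 fold change 5.73 ± 0.68 SE, adjusted p = 0.0007). Tnfrsf9 was at 366 ± 19.3 against 30 ± 4.85 (3.61 ± 0.15, adjusted p = 1.7e-07), Pdcd1 at 86 ± 13.8 against 15.9 ± 3.99 (2.43 ± 0.30) and Lag3 at 2.74 ± 1.01 against 0.562 ± 0.183 (2.28 ± 0.42, adjusted p = 0.0075). Penk, the precursor of enkephalins, was at 32 against 3.89 (3.04 ± 0.45). Dntt fell by 1.88 on the log2 scale and Klf2 by 0.91. Eomes had 4.66 ± 0.41, and 5.29 without molar-equivalent OVA replicate 3.

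TCR signalling and early activation genes gave 13 higher, 0 lower and 17 not passed (17 and 2 adjusted over the list alone; median 0.74, camera adjusted p = 9.1e-08), and the call held at adjusted p = 0.049 with an estimated correlation. Cd5, an inhibitor of receptor signalling whose level follows signal strength, was at 405 against 241 CPM (0.75 ± 0.10). Exhaustion-associated transcription factors gave 8 higher and 1 lower of 16 (11 and 1 adjusted over the list alone; camera adjusted p = 7.6e-07, adjusted p = 0.058 with an estimated correlation). Interferon-stimulated genes gave 0 higher and 14 lower of 40 (24 lower adjusted over the list alone; median -0.56, camera adjusted p = 3.5e-12, adjusted p = 0.29 with an estimated correlation). The GTPase gene Gbp2 was at 82.3 against 144 CPM (-0.81 ± 0.13). Cell cycle genes gave 21 higher and 0 lower of 50 (42 higher adjusted over the list alone; median 1.96, camera adjusted p = 1.3e-18, adjusted p = 0.29 with an estimated correlation). Naive and memory-associated genes gave 3 higher and 11 lower of 29 (4 and 18 adjusted over the list alone; camera adjusted p = 5e-06, adjusted p = 0.058 with an estimated correlation). Inhibitory receptors gave 5 higher and 0 lower of 17 (7 and 1 adjusted over the list alone; camera adjusted p = 0.021, adjusted p = 0.56 with an estimated correlation). Anergy-associated genes gave 9 higher and 3 lower of 27 (11 and 4 adjusted over the list alone; camera adjusted p = 0.056). Of the myeloid markers 0 of 24 passed (6 lower adjusted over the list alone; camera adjusted p = 2.8e-06, adjusted p = 0.55 with an estimated correlation). Of the B cell markers 0 of 20 passed as well (camera adjusted p = 0.0012 lower, adjusted p = 0.58 with an estimated correlation, and adjusted p = 0.086 without the raised-marker libraries).

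Against molar-equivalent OVA 939 of 14757 genes were called in OT-II, 581 higher and 358 lower. The count was 561 and 543 without A8B1-OVA replicate 1 or 2, and 441 and 577 without molar-equivalent OVA replicate 1 or 2. DESeq2 called 1713.

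A8B1-OVA against higher-dose OVA in OT-II cells, 3 libraries against 2, again gave Tnfrsf9, at 366 ± 19.3 CPM (SD, n = 3) against 43.2 ± 0.23 (SD, n = 2; log2 fold change 3.08 ± 0.17 SE, adjusted p = 5.9e-06). Lad1, a basement membrane anchoring protein, was at 94.8 ± 5.44 against 18.4 (2.36 ± 0.18) and Dntt at 22.1 ± 2.71 against 63.4 (-1.52 ± 0.13). These 3 genes kept their calls without any 1 library. Eomes was at 117 ± 26.5 against 13.1 ± 0.227 (3.16 ± 0.45, adjusted p = 0.0085), but not past the threshold without higher-dose OVA replicate 2 (3.15, adjusted p = 0.19) or 3 (3.18, adjusted p = 0.11). Klf2 was at 315 ± 25.4 against 593 (-0.91 ± 0.11, adjusted p = 0.0032; -0.80 and adjusted p = 0.085 without higher-dose OVA replicate 2). TCR signalling and early activation genes gave 6 higher and 0 lower of 30 (10 higher adjusted over the list alone; camera adjusted p = 2.9e-07, adjusted p = 0.053 with an estimated correlation). Naive and memory-associated genes gave 0 higher and 6 lower of 29 (9 lower adjusted over the list alone; camera adjusted p = 5.5e-07, adjusted p = 0.053 with an estimated correlation). Chemokine receptors and homing genes gave 0 higher and 6 lower of 30 (1 and 9 adjusted over the list alone; camera adjusted p = 4.2e-05, adjusted p = 0.23 with an estimated correlation). Interferon-stimulated genes gave 1 lower of 40 (7 lower adjusted over the list alone; camera adjusted p = 7.3e-11, adjusted p = 0.38 with an estimated correlation). Of the myeloid markers 0 of 24 were called (2 lower adjusted over the list alone; camera adjusted p = 0.00018 lower, adjusted p = 0.56 with an estimated correlation), and the list call held without the raised-marker libraries.

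Against higher-dose OVA 198 of 14757 genes were called in OT-II, 121 higher and 77 lower, and 1890 had an unadjusted p under 0.05. The count was 41 and 43 without A8B1-OVA replicate 1 or 2, and 6 and 22 without higher-dose OVA replicate 2 or 3. DESeq2 called 706, edgeR with only the libraries of these groups 90, and edgeR without the raised-marker libraries 122.

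**Figure D4:**
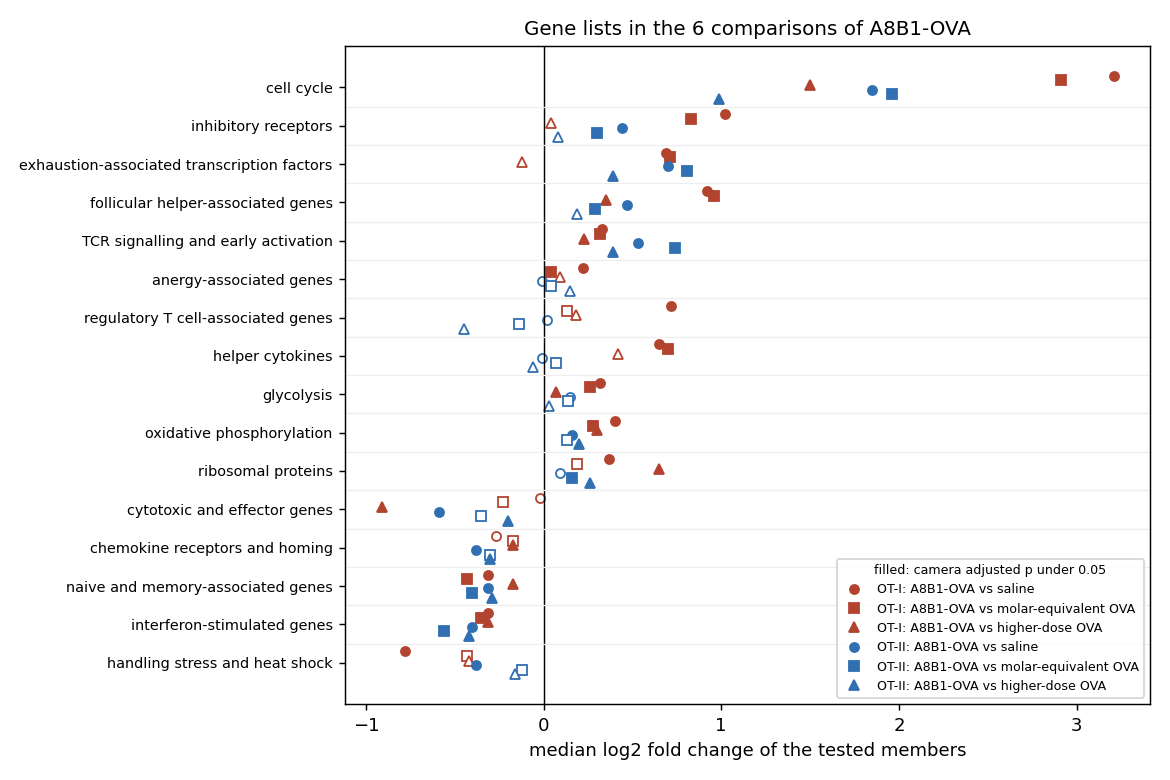
Median log2 fold change of 16 gene lists in the 6 comparisons of A8B1-OVA with another treatment, filled where the camera adjusted p is under 0.05. The cell cycle median is the highest in OT-I against saline, at 3.21, and interferon-stimulated genes lie at -0.56 in OT-II against molar-equivalent OVA.

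Free OVA against saline asks what the antigen did without A8B1. In OT-I cells the higher dose raised Zbtb32 to 41.5 ± 16.1 CPM (SD, n = 3) from 1.03 ± 0.607 (log2 fold change 5.33 ± 0.76 SE, adjusted p = 0.0045), Pdcd1 to 25.7 ± 8.71 from 3.96 ± 0.879 (2.69 ± 0.39) and Ctla4 to 62.2 ± 26.8 from 8.21 ± 2.27 (2.92 ± 0.37). Klrk1, the activating receptor NKG2D, was at 211 ± 83.1 against 21.8 ± 4.1 (3.28 ± 0.49), and Tbx21, the T-bet gene that drives effector differentiation, at 197 ± 59.5 against 42.6 ± 5.26 (2.21 ± 0.32). Cytotoxic and effector genes gave 8 higher and 0 lower of 28 (13 higher adjusted over the list alone; median 0.86, camera adjusted p = 2.3e-08, adjusted p = 0.3 with an estimated correlation). Exhaustion-associated transcription factors gave 5 higher of 16 (7 adjusted over the list alone; camera adjusted p = 1.2e-06), which held at adjusted p = 0.013 with an estimated correlation. Inhibitory receptors gave 5 higher of 17 (7 adjusted over the list alone; camera adjusted p = 2.6e-08, adjusted p = 0.075 with an estimated correlation). Cell cycle genes gave 23 higher of 50 (38 adjusted over the list alone; camera adjusted p = 1.4e-28, adjusted p = 0.22 with an estimated correlation). Egr2 had 0.25 and did not pass. In this dose group Cd4 was at 164 CPM in replicate 1 against 0.326 and 1.73 in replicates 2 and 3, and these 4 list calls held without the raised-marker libraries.

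That comparison called 339 of 14080 genes, 277 higher and 62 lower. The count was 99, 73 and 83 without saline replicate 1, 2 or 3 and 75 and 163 without higher-dose OVA replicate 2 or 3. DESeq2 called 712, edgeR with only these groups 583, and edgeR without the raised-marker libraries 128. Higher-dose against molar-equivalent OVA called 146 genes in OT-I, 118 higher and 28 lower. Itgb1, an integrin chain, was at 964 ± 443 against 142 ± 35.4 CPM (2.77 ± 0.32), a call lost with only the libraries of these groups in the fit. The count was 13 without molar-equivalent OVA replicate 1, and 14 and 28 without higher-dose OVA replicate 2 or 3. DESeq2 called 611, edgeR with only these groups 2, and edgeR without the raised-marker libraries 67. The tests of B cell (camera adjusted p = 0.00066) and erythroid markers (camera adjusted p = 0.049) passed as lower there, with 0 genes called, but not without the raised-marker libraries (adjusted p = 0.57 and 0.94). Molar-equivalent OVA against saline gave 0 genes in OT-I by edgeR, with 266 at an unadjusted p under 0.05 and 1 by DESeq2. Pdcd1 had 0.11 ± 0.38 and Lag3 1.00 ± 0.53 there, each with adjusted p = 1.

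In OT-II cells higher-dose OVA against saline called 4 of 14757 genes by edgeR, 3 higher and 1 lower, with 872 at an unadjusted p under 0.05 and 90 by DESeq2. They included Cxcr5, at 52.5 ± 0.874 CPM (SD, n = 2) against 8.53 ± 2.85 (SD, n = 3; log2 fold change 2.62 ± 0.35 SE, adjusted p = 0.033), P2rx7, an ATP-gated channel (1.48 ± 0.20, adjusted p = 0.034), and Irf2bp2, a co-repressor (-1.06 ± 0.13, adjusted p = 0.033). The count was 0 without saline replicate 2 or 3, or without higher-dose OVA replicate 2 or 3, so that each of these calls was lost there. No cell cycle gene was called (0 of 50; camera adjusted p = 2.3e-10, adjusted p = 0.67 with an estimated correlation). Higher-dose against molar-equivalent OVA gave 0 genes by edgeR, with 792 at an unadjusted p under 0.05 and 47 by DESeq2, and B cell markers passed as lower (camera adjusted p = 0.0055), but not without the raised-marker libraries (adjusted p = 0.32). Molar-equivalent OVA against saline also gave 0 by edgeR, with 577 at an unadjusted p under 0.05 and 22 by DESeq2, and it gave 1 without saline replicate 1, 2 or 3.

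The responses of both cell types were set side by side over the 13905 genes tested in each. Against saline 340 genes were higher in both, where independent calls would give 45.3, 165 were lower in both (18.9), and 6 went opposite ways. The log2 fold changes had r = 0.476 across genes, which are not independent replicates. Against molar-equivalent OVA 309 were higher in both (37.9) and 141 lower in both (14.7), and against higher-dose OVA 55 (1.98) and 11 (0.604).

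The test of the difference between the responses, OT-I minus OT-II, asks which genes A8B1-OVA moved unequally in CD8 and CD4 cells. Against saline, Nrp1 differed by 4.59 ± 0.46 (log2, SE, adjusted p = 4.2e-05), at 47.7 ± 0.601 against 3.05 ± 0.182 CPM in OT-I and 17.5 ± 1.79 against 26.5 ± 5.51 in OT-II (SD, n = 3 each). Lag3 differed by 4.48 ± 0.66 (adjusted p = 0.0018) and Itgb1 by 2.53 ± 0.38 (adjusted p = 0.002). Eomes differed the other way, by -4.18 ± 0.46 (adjusted p = 8e-05), at 112 ± 2.35 against 64.8 ± 6.78 CPM in OT-I. Pdcd1 (2.16, adjusted p = 0.079), Izumo1r (2.10, adjusted p = 0.058), Tox (-0.48, adjusted p = 0.2) and Egr2 (-0.42, adjusted p = 0.79) did not pass in this fit, which holds no block for pools of mice. Such a block, tried although pairing is not established, gave 23 named genes a call over the differences tested and took 1 away. Higher-dose free OVA also raised Nrp1 (3.57 ± 0.4) and Lag3 (3.81 ± 0.53) against saline in OT-I, with Lag3 at 0.27 in OT-II. Differences between the cell types were not tested for free OVA, so these are not shown to be particular to A8B1-OVA. Inhibitory receptors gave 2 higher of 17 (5 adjusted over the list alone; camera adjusted p = 0.0007, adjusted p = 0.39 with an estimated correlation). In the cell cycle list it was 0 of 50 (1 adjusted over the list alone; camera adjusted p = 9.9e-10, adjusted p = 0.39 with an estimated correlation). Nrp1 spans 128358604 to 128503363 of chromosome 8 and Eomes 118478212 to 118486132 of chromosome 9.

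For this difference 66 of 15235 tested genes were called, 47 higher and 19 lower. The count was 40, 39 and 111 without OT-I A8B1-OVA replicate 1, 2 or 3, 40, 30 and 32 without OT-I saline replicate 1, 2 or 3, and 37 without OT-II A8B1-OVA replicate 3. DESeq2 called 253, and edgeR without the raised-marker libraries 31.

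The same test against molar-equivalent OVA called 43 genes, 24 higher and 19 lower, with Nrp1 at 4.22 ± 0.46 (adjusted p = 0.00015) and Gata3, the master factor of type 2 helper cells, at 0.87 ± 0.12 (adjusted p = 0.0012). Gm13256 lies antisense to Gata3. The count was 24 without OT-I A8B1-OVA replicate 2, 16 and 96 without OT-I molar-equivalent OVA replicate 1 or 2, 28, 21 and 21 without OT-II A8B1-OVA replicate 1, 2 or 3, and 22 and 28 without OT-II molar-equivalent OVA replicate 2 or 3. DESeq2 called 174.

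Against higher-dose OVA the test called 1 gene, Eomes (-3.24 ± 0.48, adjusted p = 0.026), with 786 at an unadjusted p under 0.05 and 33 by DESeq2. The count was 0 without OT-I A8B1-OVA replicate 1 or 2, OT-I higher-dose OVA replicate 2, OT-II A8B1-OVA replicate 1 or 2, or OT-II higher-dose OVA replicate 2 or 3, where Eomes lay between -3.27 and -2.98 with adjusted p from 0.059 to 0.36. It was 3 without OT-I A8B1-OVA replicate 3 and 2 without OT-I higher-dose OVA replicate 1 or 3. Of the exhaustion-associated transcription factors 1 of 16 was lower (3 lower adjusted over the list alone; camera adjusted p = 0.00013), and this held at adjusted p = 0.017 with an estimated correlation.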

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

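The tests of the difference between the OT-I and OT-II responses were planned, whereas the search for the source of Gm17571, the test of NK cell markers and the breakdown of splits by their balance were chosen after the result was seen.

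The size of the response to A8B1-OVA differed between OT-I and OT-II cells by an interaction test for 66 genes against saline, 43 against molar-equivalent OVA and 1 against higher-dose OVA. Against saline the log2 difference, OT-I minus OT-II, was 5.92 for Zbtb32 (5.19 without OT-II saline replicate 1), 4.59 for Nrp1, 4.48 for Lag3, 2.72 for Capn3 and 2.77 for Chst2, and it was 2.37 for Ctla4. It was -4.18 for Eomes, -1.91 for Cxxc5, a zinc finger protein, -1.6 for Pmepa1, which restrains TGF-beta signalling, and -1.31 for Igflr1. Nrp1, Lag3, Capn3, Eomes, Cxxc5 and Igflr1 kept their calls without any 1 library. Higher-dose free OVA against saline also raised Zbtb32, Nrp1, Lag3, Ctla4 and Chst2 in OT-I. No difference between the cell types was tested for free OVA, so those of these genes are not shown to be particular to A8B1-OVA. Capn3 overlaps Ganc, and Igflr1 shares 95.4% of its sequence with Gm49396, so that reads of these genes cannot be assigned with certainty.

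Against saline the call of Chst2, a sulfotransferase, was lost without OT-I A8B1-OVA replicate 1 or 2, OT-I saline replicate 2 or 3, OT-II A8B1-OVA replicate 1 or 3, or OT-II saline replicate 1 or 2, at 2.5 to 2.78 with adjusted p from 0.074 to 0.13. That of Pmepa1 was lost without OT-I A8B1-OVA replicate 2, OT-I saline replicate 1, 2 or 3, OT-II A8B1-OVA replicate 1 or 2, or OT-II saline replicate 2 or 3, at -1.63 to -1.49 with adjusted p from 0.055 to 0.083. That of Ctla4 was lost without OT-I A8B1-OVA replicate 1, OT-I saline replicate 2 or 3, OT-II A8B1-OVA replicate 3, or OT-II saline replicate 1, at 2.15 to 2.35 with adjusted p from 0.053 to 0.067.

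Against molar-equivalent OVA the difference was 4.22 for Nrp1, 3.17 for Capn3, 2.76 for Chst2 and 1.97 for Itgb1. It was -3.98 for Eomes (-4.59 without OT-II molar-equivalent OVA replicate 3), -2.51 for Crtam, a surface molecule of activated cytotoxic cells, -1.81 for Cxxc5 and -1.31 for Gsto1. The call of Chst2 was lost without OT-I A8B1-OVA replicate 1 or 2, OT-I molar-equivalent OVA replicate 1 or 2, OT-II A8B1-OVA replicate 1 or 3, or OT-II molar-equivalent OVA replicate 1 or 3, at 2.38 to 2.77 with adjusted p from 0.058 to 0.15, and its value was 3.49 without OT-I molar-equivalent OVA replicate 3. That of Itgb1 was lost without OT-I A8B1-OVA replicate 3, OT-I molar-equivalent OVA replicate 1, OT-II A8B1-OVA replicate 1, 2 or 3, or OT-II molar-equivalent OVA replicate 2 or 3, at 1.68 to 2.03 with adjusted p from 0.05 to 0.092. That of Crtam was kept only without OT-I molar-equivalent OVA replicate 2 or OT-II molar-equivalent OVA replicate 1, and lay at -2.68 to -2.23 with adjusted p from 0.055 to 0.18 without the others. That of Gsto1 was lost without OT-I A8B1-OVA replicate 2 or 3, OT-I molar-equivalent OVA replicate 1 or 3, OT-II A8B1-OVA replicate 1 or 2, or OT-II molar-equivalent OVA replicate 1 or 3, at -1.36 to -1.12 with adjusted p from 0.053 to 0.094.

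Against higher-dose OVA it was -3.24 for Eomes. This call was lost without OT-I A8B1-OVA replicate 1 or 2, OT-I higher-dose OVA replicate 2, OT-II A8B1-OVA replicate 1 or 2, or OT-II higher-dose OVA replicate 2 or 3, at -3.27 to -2.98 with adjusted p from 0.059 to 0.36.

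Of 60 drawn splits of treatment within the cell types, 9 gave as many genes as the 66 called against saline, the real one included, with 3085 in the highest of the others. For the 43 against molar-equivalent OVA it was 8 of 60, with 3117 in the highest, so that chance is not excluded by these counts. The splits as large as the real one divide the treatments unequally in the cell types, so that a structure of the samples, the response to treatment shared by both cell types, enters the contrast by design. Among the 60 drawn splits 19 had an equal division in both cell types, and more such splits exist that were not drawn. The 19 are too few for a share under 0.05, which is a limit of the draw. The real one gave 66 against saline and 43 against molar-equivalent OVA, and the highest other 0 for each.

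The first pattern weighed was Cd4 in OT-I higher-dose OVA replicate 1. Over 9 other genes at least 10 times higher in OT-II, the median excess was 31.4% of their OT-II level (quartiles 29 and 35.3), against 23.7% for Cd4 and -0.8% to 1.1% in the other 11 OT-I libraries. Cd8a was at 786 CPM there against 1070, 26.8% lower. These values are consistent with RNA of CD4 T cells in this library, although the sort on OT-I cells would remove them. Whether the mixing happened at the sort or later stays open.

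The second pattern was the lower myeloid markers with A8B1-OVA than with saline in OT-II, although a sort on T cells would remove myeloid cells; the list was also lower against molar-equivalent and higher-dose OVA, where saline is not compared (camera adjusted p = 4.9e-08 and 7.7e-07 without the raised-marker libraries, adjusted p = 0.55 and 0.56 with all libraries and an estimated correlation). Without OT-II saline replicate 1, 2 of the 7 called markers stayed called, Ngp and Ltf, and the other 5 lost their calls with smaller folds and 1 library fewer, at -6.84 to -0.88 (SE 0.34 to 1.89) against -11.79 to -1.99 (SE 0.53 to 2.92). The median of the 7 went from -5.07 to -2.27 and that of all 24 from -1.51 to -0.38. By the rule set beforehand, the 2 calls kept left this cause undecided. The summed myeloid markers were at 359 to 459 CPM with A8B1-OVA. They were at 496 and 532 in saline replicates 2 and 3, 596 to 609 with molar-equivalent OVA, and 526 and 536 with higher-dose OVA. These sums argue against RNA of myeloid cells in saline replicate 1 as the whole cause of the lower list. A part from that library stays open. Gm17571 was also at 2040, 81.8 and 2.55 CPM in the OT-II saline libraries, and Cd80 at 430, 54.8 and 11, with up to 19.6 outside them. Each was highest in saline replicate 1, as the first prediction for myeloid RNA in that library asked. A comparison with Lyz2, a macrophage and granulocyte gene, was added after that result. Gm17571 reached at most 0.902 CPM in the 20 libraries outside this group. Yet 10 of them had Lyz2 at or above the 44 CPM of OT-II saline replicate 2. This argues against myeloid cells with Lyz2 as the source of Gm17571, while myeloid cells without Lyz2 were not tested. No biological explanation was tested.

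The third pattern was the lower level of cytotoxic genes in OT-I with A8B1-OVA than with higher-dose OVA. Without the library with raised Cd4 the list median was -1.18 (-0.91 with all libraries), and 6 of the 10 lower members stayed called in a fit that called 109 genes in all. The other 4 lost their calls with 1 library fewer, at a median of -2.3 (SE 0.49) against -2.08 (SE 0.46). The pattern thus did not rest on this library alone. Its test was weak, because this library was already the lowest of the higher-dose ones for Klrk1 (133 CPM against 289 and 205). For Gzmb it was not (47.9 against 136 and 41.5). The list was not tested without replicate 2, where both genes were highest. After thinning all OT-I libraries to the smallest total 9 of the 10 were still lower, which argues against depth. The NK cell list was lower too with A8B1-OVA than with higher-dose OVA (camera adjusted p = 0.032), a call that was lost with an estimated correlation. Its 13 markers outside the cytotoxic list and not called there had a median of -0.51 (quartiles -0.81 and 0.16) with higher-dose OVA against saline. Among these Eomes was higher (0.92, adjusted p = 0.026), and the other 12 lay under 10 CPM. NK cells, which the sort on OT-I cells would remove, therefore cannot be told apart from a change in the OT-I cells. Dose and form of the antigen differ together and were not tested.

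Each comparison of 3 against 3 libraries has 10 splits, too few for a share under 0.05. In OT-I the real split against saline gave 1620 genes and the highest other 0, in 1 of 10 splits as large. Against molar-equivalent OVA it gave 1496 and the highest other 765, and against higher-dose OVA 339 and 0. Higher-dose OVA against saline gave 339 and 0, and against molar-equivalent OVA 146 and 0. In OT-II the real split gave 1074 against saline and 939 against molar-equivalent OVA, with 0 in the highest other for each. For molar-equivalent OVA against saline the real count of 0 was reached by 10 of 10 splits in both cell types, with 4 in the highest other in OT-I and 0 in OT-II.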

How the results depend on the processing

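Robust empirical Bayes, the fits without raised-marker libraries and the thinned OT-I libraries were chosen after seeing the data, as was the choice of the 5 raised-marker libraries. Of the alternatives to the 15 counts, besides those that leave out 1 library, 71 stayed within 1.5 times. The others did not, among them most of those with DESeq2, and their counts are given below. No alternative scaling moved the median log2 fold change of all genes by more than 0.1.

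The ranges without 1 library in OT-I were 674 (without A8B1-OVA replicate 2) to 2569 (without A8B1-OVA replicate 3) against saline, 575 to 2181 against molar-equivalent OVA and 38 to 1487 against higher-dose OVA, with the same libraries at the ends. Higher-dose OVA against saline had 73 (without saline replicate 2) to 303 (without higher-dose OVA replicate 1), against molar-equivalent OVA 13 (without molar-equivalent OVA replicate 1) to 153 (without its replicate 3), and molar-equivalent OVA against saline 0 throughout. In OT-II A8B1-OVA gave 578 (without saline replicate 3) to 1011 (without A8B1-OVA replicate 3) against saline, 441 (without molar-equivalent OVA replicate 1) to 968 (without A8B1-OVA replicate 3) against molar-equivalent OVA, and 6 (without higher-dose OVA replicate 2) to 210 (without A8B1-OVA replicate 3) against higher-dose OVA. Molar-equivalent OVA against saline gave 0 to 1, higher-dose OVA against saline 0 to 4 and against molar-equivalent OVA 0 to 0. The differences in response gave 30 (without OT-I saline replicate 2) to 111 (without OT-I A8B1-OVA replicate 3) against saline, 16 to 96 (without OT-I molar-equivalent OVA replicate 1 and 2) against molar-equivalent OVA, and 0 to 3 against higher-dose OVA. Where OT-II higher-dose OVA was left with 1 library, it was assumed to vary like the other groups. A smaller count with fewer libraries follows in part from their number, whereas for the larger counts without OT-I A8B1-OVA replicate 3 the cause was not tested.

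Without raised-marker libraries OT-I gave 977 for A8B1-OVA against saline, 62 against higher-dose OVA, 128 for higher-dose OVA against saline and 67 against molar-equivalent OVA. OT-II gave 122 for A8B1-OVA against higher-dose OVA and 2 for higher-dose against molar-equivalent OVA, and the differences in response gave 31 against saline and 2 against higher-dose OVA. With DESeq2 OT-I gave 2457, 1202, 1, 712 and 611 for A8B1-OVA against molar-equivalent and higher-dose OVA, molar-equivalent and higher-dose OVA against saline, and higher-dose against molar-equivalent OVA. OT-II gave 1892, 1713 and 706 for A8B1-OVA against saline, molar-equivalent and higher-dose OVA, and 22, 90 and 47 for the comparisons without it, in the order given for OT-I; the differences in response gave 253, 174 and 33. With only the libraries compared, OT-I gave 575 and 210 for A8B1-OVA against molar-equivalent and higher-dose OVA, 583 for higher-dose OVA against saline and 2 against molar-equivalent OVA, and OT-II gave 90 for A8B1-OVA against higher-dose OVA and 0 for higher-dose OVA against saline. Without a filter OT-II higher-dose OVA gave 7 against saline and 2 against molar-equivalent OVA, and with robust empirical Bayes 2 against molar-equivalent OVA. For all of these the cause was not tested.

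The same numbers did not pair the samples across treatments (r of -0.31 to 0.13 across genes, 2 of 33 pairs over 0.1), and between OT-I and OT-II 6 of 11 pairs lay over 0.1 (-0.03 to 0.28); genes are not independent replicates, and pairing is not established. With replicate number as a block OT-II gave 44 for A8B1-OVA against higher-dose OVA, 1 for molar-equivalent OVA against saline and 0 for higher-dose OVA against saline. With a block for pools the differences in response gave 101, 78 and 9; of the named genes 23 gained a call and 1 lost it, and the cause was not tested.

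The direction of 1 list was reversed: CD4 lineage genes in OT-I, higher-dose against molar-equivalent OVA, without raised-marker libraries, of which 1 had raised Cd4 (adjusted p = 0.975). Of 134 list calls 101 held without raised-marker libraries, 132 with RLE factors, 127 with the replicate block and 51 with fry; leaving out 1 library was not run for lists. Depth limits the genes near the filter: after thinning OT-I to its smallest library 269 of the named calls held and 7 did not. Single libraries mattered more. For A8B1-OVA in OT-I, 50 of 74 named calls against saline, 51 of 76 against molar-equivalent OVA and 12 of 51 against higher-dose OVA held without any 1 library. It was 5 of 31 for higher-dose against molar-equivalent OVA in OT-I, and 55 of 74 for A8B1-OVA against saline in OT-II.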

Other observations

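The fits without raised-marker libraries mentioned here were chosen after the result was seen. Some genes outside the named patterns of inhibition and activation moved strongly with A8B1-OVA. Plaur, the urokinase receptor, fell in OT-I from 40.2 ± 10.6 to 8.05 ± 2.14 CPM (SD, n = 3; log2 fold change -2.32 ± 0.23, SE, adjusted p = 8.7e-05) against saline, and Ifngr2, a chain of the interferon gamma receptor, from 64.8 ± 6.99 to 19 ± 0.52 (-1.77 ± 0.18). Igfbp4, a binding protein of insulin-like growth factors, fell from 483 ± 26.4 to 142 ± 48.7 (-1.76 ± 0.23). Itgb1 rose from 115 ± 5.93 to 564 ± 182 (2.29 ± 0.32) and Cxcr3, a chemokine receptor of effector cells, from 55.3 to 172 (1.64 ± 0.24). Higher-dose free OVA against saline in OT-I moved Plaur (-1.36), Igfbp4 (-1.24), Itgb1 (3.07) and Cxcr3 (2.27) the same way. Their changes are thus not shown to be particular to A8B1-OVA.

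In OT-II, Pou2af1, a co-activator known from B cells, was at 86.6 against 9.9 CPM with A8B1-OVA and saline (3.13 ± 0.38), and Lad1 at 94.8 ± 5.44 against 8.44 (3.49 ± 0.17). Ly6c1 fell by 1.82 on the log2 scale and Pdlim4 by 1.78; Ly6c1 shares 46.8% of its sequence with Ly6c2. Prdm1, the Blimp-1 gene of terminal differentiation, was at 4.63 against 11.7 CPM with A8B1-OVA and molar-equivalent OVA (-1.33 ± 0.23, adjusted p = 0.0052).

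Molar-equivalent OVA against saline had 9 lists past the camera test in OT-I and 4 in OT-II, with 0 genes called. With an estimated correlation none of them passed (adjusted p = 0.8 to 0.86 in OT-I and 0.99 in OT-II). In OT-I the B cell markers were higher (adjusted p = 2.6e-07, and 0.019 without raised-marker libraries), with sums of 440, 3530 and 1040 CPM against 994, 533 and 498 in saline, so that replicate 2 stood apart. The tests of cell cycle (adjusted p = 0.00069), oxidative phosphorylation (0.00033) and ribosomal protein genes (0.00089) also passed as higher and held without raised-marker libraries. Those of TCR signalling and early activation (lower, adjusted p = 0.0021), inhibitory receptors (higher, 0.024), regulatory T cell-associated genes (higher, 0.025), handling stress and heat shock (lower, 0.0016) and myeloid markers (higher, 0.012) did not hold there (adjusted p = 0.49, 0.2, 0.32, 0.49 and 0.28). In OT-II handling stress and heat shock genes (lower, adjusted p = 0.00085) and B cell markers (higher, 0.033, and 0.0075 without raised-marker libraries) held. TCR signalling and early activation genes and erythroid markers (both lower, adjusted p = 0.033) did not (adjusted p = 0.35 and 0.61).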
